A study of Danio rerio with 4 samples.

How the data were processed

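Polyadenylated RNA of zebrafish samples labelled liver was sequenced in 4 libraries, 1 for the control and 1 for each of 12, 24 and 48 h of 0.8 mM binaprofen, per the labels. The strain label carries the name of a laboratory mouse strain and the cell type label names liver progenitors for every sample, while the gene entries are those of zebrafish, so neither label was used to describe the samples. A single deposited table held the values of all libraries, with a column of each kind per library named for its group.

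Per the file headers, the authors gave FPKM values per gene and library, and these were used as deposited. The deposited count columns are a library-scaled signal and not raw counts, since every column totals about 21.7 M and most values are whole multiples of 1 step per library. Dividing by that step gave estimated reads, of which 98.3% to 99.1% of values above 0 came out whole within 0.05 of a read, and which total 24.3, 18.1, 29.4 and 17.1 M reads in the control, 12 h, 24 h and 48 h libraries. A floor of 3 reads corresponds to 0.102 to 0.176 FPKM for a gene of 1 kb. The reads were used for depth, for exact binomial intervals of shares and for 95% intervals of read ratios, which cover counting error only. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.6 and genome build Zv9 without their roles. The tool and annotation of the gene quantification are not given in the sources used here, nor is the use of strand.

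The comparisons, gene lists, named-gene rule and all alternatives except those named as added were fixed before the data were examined. The design had foreseen scaled counts if whole-number counts were given, and FPKM otherwise. As no column held whole numbers, FPKM was the main value and the scaled counts relative to their library total the alternative. The value compared was log2(FPKM + 1), and a fold on this scale understates the change of low genes. Entries with a mean of at least 1 FPKM over the 4 libraries were kept, 17500 of 25861. An entry was counted as higher or lower at a difference of at least 1, which is 2-fold. With 1 library per group no p-value was computed. Entries were named by their current symbol through their Entrez gene number (assembly GRCz12tu, used for names only), which matched 21395 entries or 82.7%. The others kept the deposited symbol. Coordinates are those of the deposited table.

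The 43 fixed lists cover liver functions, stress and cell death pathways and markers of other organs and cells. The list of the mitochondrial genome had 0 entries in the table and gave no result. For each other list the median log2 difference is given with an exact order-statistic interval over members, and its percentile among 10000 random lists of the same size matched on mean level in 20 bins describes these libraries only. Of the 126 medians against the control library, 80 lay outside the central 95% of random lists, against 6.3 for independent values. The 6.3 is no measure of chance here, since members of an organ list vary together, lists share members and the comparisons share the control library. The genes named are the 10 highest and 10 lowest per exposure time with a gene symbol that is not a placeholder and a mean of at least 5 FPKM, the 10 higher and 10 lower at all 3 times with the largest smallest difference, the members of each list with the largest difference in either direction and the highest level, the 10 most abundant genes of each library, the 5 highest and 5 lowest between exposure times, and further list members where needed to describe a count. Comparisons that share the control library were set against 100 simulations of unchanged libraries, with noise drawn from the spread of the 3 treated libraries around their mean within bins of level. That spread holds the differences between these libraries as well, so the simulated values are high.

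The steps were tested on simulated reads. Both simulated libraries were drawn from the control profile with counting error only, and the changed genes had at least 5 FPKM in the control library. In a simulation of 12 h against control over 17500 entries, 98.0% of 100 genes changed 3-fold and 100% of 100 genes changed 6-fold were called. Of 17300 unchanged entries, 24 passed 2-fold. These values leave out differences between fish and in tissue content, so they are not error rates of the 2-fold rule in these libraries. Alternatives were median-ratio scaling, trimmed-mean scaling, the scaled counts, pseudocounts of 0.1 and 5, no filter, a mean of at least 10 FPKM, the mean over list members, named symbols only, and calls at 2 of the 3 times. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.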

Results

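Gene expression was profiled by sequencing of polyadenylated RNA from zebrafish samples labelled liver. Adult or larval stage and sex are not stated in the labels used here. The fish had been exposed to 0.8 mM binaprofen, a drug studied here for liver injury, for 12, 24 or 48 h, and 1 control library came from fish without the drug, with no time given. Each of the 4 groups held 1 library, so none of the differences below has a replicate check and no test across genes was made. The table listed 25861 gene entries, of which 17500 had a mean of at least 1 FPKM (fragments per kilobase of transcript, scaled to library size) over the 4 libraries. The estimated depth was 24.3 M reads in the control library, 18.1 M at 12 h, 29.4 M at 24 h and 17.1 M at 48 h. Intervals given for reads cover counting error only. The series title names the mitochondrial pathway as the question, and the comparisons are of each exposure time with the control library and of the times with each other.

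Genes that mark organs differed widely between the libraries. Ovary markers had a median of 621 FPKM in the control library and 995 at 24 h, against 5.95 at 12 h and 4.69 at 48 h (27 genes). Among them was zp3, an egg coat protein gene, with 4272, 15.7, 5729 and 26.8 FPKM in the control, 12 h, 24 h and 48 h libraries. Hepatocyte genes showed another order, with a median of 2.31 FPKM at 24 h against 66.3 in the control library, 174 at 12 h and 299 at 48 h (75 genes). Exocrine pancreas markers had medians of 178, 863, 2.24 and 296 FPKM and intestine markers 30.9, 111, 0.154 and 170 FPKM in the same order of libraries. Testis markers had a median of 21.2 FPKM at 12 h and at most 0.542 FPKM in the other libraries (19 genes). Skeletal muscle markers were highest in the control library, at 35.9 FPKM, against 2.03, 0.477 and 2.79 FPKM (34 genes). Across the 17500 entries, which are not independent replicates, log2 levels of the control library correlated most with 24 h (Pearson r = 0.870) and those of 12 h most with 48 h (r = 0.853), while 12 h and 24 h gave r = 0.319.

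**Figure D1:**
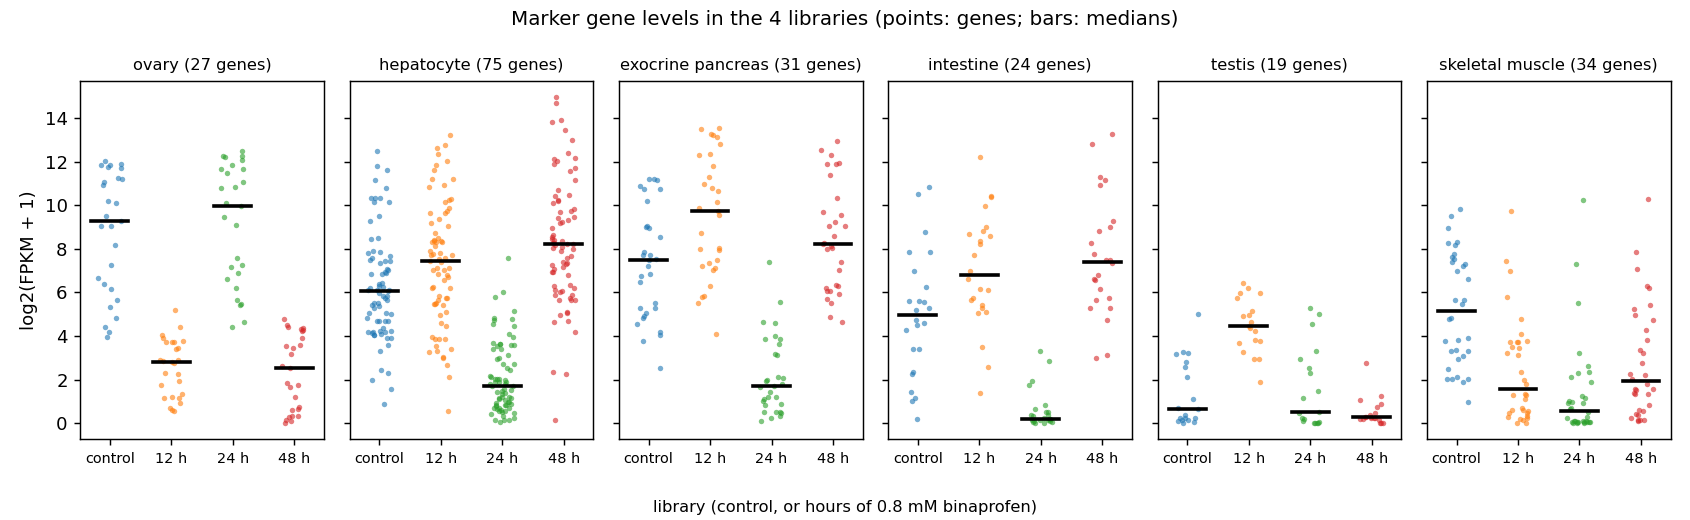
Levels of marker genes of 6 organs, as log2(FPKM + 1) on the vertical axis, in the control library and after 12, 24 and 48 h of 0.8 mM binaprofen on the horizontal axis; each point is a gene and each bar the median of the list. Ovary markers stand high in the control and 24 h libraries (medians of 621 and 995 FPKM), and hepatocyte, exocrine pancreas and intestine markers stand low at 24 h.

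At 12 h drug metabolism, antioxidant and immune cell genes stood higher than in the control library, and vitellogenin, ovary and cell cycle genes lower. The myeloid peroxidase gene mpx (chromosome 10, 6767039 to 6816036, build Zv9) had 1576 FPKM at 12 h against 0.319 in the control library, with 0.221 at 24 h and 2.34 at 48 h, and its read ratio had a 95% interval of 3217 to 7616. The gene of the vitamin D hydroxylase cyp24a1 had 711 against 3.12 FPKM, the growth factor binding protein gene igfbp1a 1215 against 10.1 FPKM, the cytochrome P450 gene cyp2k18 1767 against 14.9 FPKM, the anion exchanger gene slc26a3.1 157 against 0.259 FPKM and cbln7 576 against 0.393 FPKM. The ranking also held lect2.3, a leukocyte chemotaxin gene (326 against 0.203 FPKM, the latter on 2 reads), and microRNA entries with at most 4 reads, for which no fold is given. The lowest values included those of vitellogenins, the yolk protein precursors made by the liver of laying females. In the control library vtg1 (chromosome 22, 25203629 to 25210658) took 2.26% of reads (exact binomial interval 2.25% to 2.26%) at 6019 FPKM, against 4.41 FPKM at 12 h. The egg coat gene zp3e had 4279 against 12.9 FPKM, cldnd 2144 against 6.27 FPKM and tmsb5 4281 against 10.4 FPKM. The vitellogenin, egg coat, elastase and trypsin genes form families of similar sequence, so the division of reads among their members is uncertain.

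In all, 5885 entries were at least 2-fold higher and 4115 at least 2-fold lower at 12 h, on the log2(FPKM + 1) scale. The median entry stood 0.27 higher, against -0.12 with median-ratio and -0.25 with trimmed-mean scaling. The share of higher entries among those past 2-fold was 58.9%, against 45.8% and 41.3% under these scalings. Genes of drug metabolism other than aryl hydrocarbon receptor targets had a median log2 difference of 1.99 (95% interval 1.39 to 2.26), with 76 of 112 members at least 2-fold higher and 9 lower. Glutathione and antioxidant genes had a median of 1.44 (1.08 to 2.02), with 35 of 50 members higher and 2 lower. Among them were gpx1b (722 against 20.8 FPKM), the conjugate exporter gene abcc2 (1051 against 18.7 FPKM) and the haem oxygenase gene hmox1a (32.0 against 0.561 FPKM). The median was 1.09 for fatty acid oxidation (26 of 47 members higher), 1.59 for lipogenesis (21 of 29), 1.03 for cholesterol synthesis (16 of 32), 1.29 for bile acid synthesis and transport (13 of 26) and 0.99 for gluconeogenesis and glycogen (-0.61 to 1.75, 13 of 28, with 7 lower). In these libraries the hepatocyte list stood 0.87 higher at 12 h, with 35 of 75 members higher and 4 lower, the exocrine pancreas list 2.31 higher and the intestine list 2.12 higher. With median-ratio and trimmed-mean scaling the hepatocyte list stood at 0.44 and 0.28, fatty acid oxidation at 0.68 and 0.53, cholesterol synthesis at 0.66 and 0.55 and gluconeogenesis at 0.60 and 0.47. Trimmed-mean scaling also gave 0.86 for glutathione, 1.02 for lipogenesis and 0.79 for bile acid genes.

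Genes of immune cells and of inflammation stood higher at 12 h. Macrophage markers had a median log2 difference of 2.56 (24 of 27 members higher), neutrophil markers 2.09 (12 of 13) and lymphocyte markers 1.86 (17 of 19). Interferon-stimulated genes had 1.96 (27 of 34) and acute phase and cytokine genes 1.74 (35 of 47). The exocrine pancreas and intestine lists stood at 2.31 and 2.12 in the same comparison, and ovary markers were lower. These medians therefore cannot tell an immune response from a different tissue content of the libraries. The medians of biliary and progenitor markers (1.55), endothelial markers (1.69), stellate and fibroblast markers (0.93) and erythrocyte markers (1.36) were also above 0. The immediate early gene list had 1.51, hypoxia 1.26, circadian clock 0.97, with an interval from -0.05, and autophagy and lysosome 0.83. With median-ratio and trimmed-mean scaling stellate and fibroblast markers had 0.47 and 0.33, the circadian clock 0.61 and 0.49 and autophagy 0.40 and 0.25. Trimmed-mean scaling also gave 0.95 for biliary, 0.78 for erythrocyte, 0.73 for hypoxia and 1.00 for immediate early genes. Cell cycle genes were lower, with a median of -2.53 (-3.09 to -1.40) and 31 of 41 members at least 2-fold lower, as were ovary markers, with -7.20 (-8.00 to -5.21) and 25 of 27 members lower. Cyclin B1, ccnb1, had 33.4 FPKM at 12 h against 1144 in the control library. Testis markers had a median of 3.62 (1.83 to 4.23), with 16 of 19 members higher, among them the ciliary gene tekt1 at 62.5 against 0.169 FPKM.

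At 24 h the profile was nearest to that of the control library, and genes of the liver, gut and pancreas, vitellogenins and muscle markers were lower. Vitellogenins were 6 of the 10 lowest named genes, and their list, with oestrogen-responsive genes, had a median log2 difference of -8.05. The hepatocyte list had a median log2 difference of -4.13 (-4.42 to -3.86), with 72 of 75 members at least 2-fold lower and 0 higher. The liver fatty acid binding protein gene fabp10a had 14.4 FPKM at 24 h against 5857 in the control library (read ratio interval 0.00196 to 0.00286), and the apolipoprotein gene apoea 1.64 against 1290 FPKM. The exocrine pancreas list stood at -5.85 (29 of 31 members lower), with prss59.1 at 7.62 against 1749 FPKM, and the intestine list at -4.50 (22 of 24 lower), with fabp2 at 2.82 against 1490 FPKM. Ovary markers had a median of 0.42 (0.34 to 0.58), with 1 of 27 members at least 2-fold higher, and cell cycle genes 0.56 (0.43 to 0.70), with 4 of 41 higher. Entries at least 2-fold higher numbered 607 and those lower 2736, a share of 18.2% higher that was 29.4% with median-ratio scaling. The median entry stood at 0.03, against 0.19 and 0.09 with median-ratio and trimmed-mean scaling. The highest named genes with over 100 reads at 24 h were ms4a17a.9 (34.9 against 0.869 FPKM), cyp2p10 (23.1 against 0.696), ascc1 (145 against 12.2), the collagenase gene mmp13a (12.1 against 0.320), bnip4 (14.7 against 0.789) and tdg.2 (12.1 against 0.616). The ranking also held the microRNA entries mir150, mir92a-2, mir34a and mir126a, each with 1 or 2 reads at 24 h and 0 in the control library, for which no fold is given.

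Lists of liver functions were below 0 at 24 h, as the hepatocyte list was. Drug metabolism genes had a median of -1.40 (-1.62 to -1.08), with 68 of 112 members lower and 8 higher, bile acid genes -2.89 (21 of 26 lower), gluconeogenesis and glycogen -0.75 (12 of 28), lipogenesis -0.57 (13 of 29), fatty acid oxidation -0.42 (18 of 47) and aryl hydrocarbon receptor targets -0.73 (4 of 9). The glutathione list had -0.13 and the cholesterol list -0.07, values whose sign changed with the scaling, with 15 of 50 and 8 of 32 members lower. Markers of stellate cells and fibroblasts (-1.94), erythrocytes (-1.73), biliary and progenitor cells (-1.58), macrophages (-0.94), endothelium (-0.56), neutrophils (-0.49) and lymphocytes (-0.21) were all below 0, as were interferon-stimulated (-0.70), acute phase (-0.59), glycolysis (-0.52), hypoxia (-0.43), circadian clock (-0.36), metal response (-0.37), immediate early (-0.27) and prostanoid genes (-0.25). Of these, the intervals of the lymphocyte, glycolysis, metal response and prostanoid lists reached above 0, as that of the aryl hydrocarbon receptor targets did. Low control levels limited how far the cell markers could fall. All 19 lymphocyte and 24 endothelial markers, 24 of 27 macrophage and 12 of 13 neutrophil markers were too low to reach the hepatocyte median. Their smaller medians therefore do not show that this RNA was kept at 24 h. Median-ratio scaling gave -0.24 for fatty acid oxidation, -0.34 for glycolysis, -0.25 for hypoxia, -0.23 for the circadian clock, -0.18 for metal response and -0.15 for prostanoid genes. Ribosomal protein genes had -0.90, with 29 of 84 members at least 2-fold lower. The proteasome list was above 0, at 0.47 (0.40 to 0.61), with 1 of 51 members at least 2-fold higher and 3 lower. Autophagy and lysosome genes had -0.07, a sign that changed with the scaling, and testis markers 0.00, against 0.11 with median-ratio scaling.

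At 48 h intestine, drug metabolism, bile acid and hepatocyte genes stood higher than in the control library, and vitellogenin and ovary genes lower. The iron hormone gene hamp (chromosome 16, 53816317 to 53818985) had 544 FPKM at 48 h against 0.585 in the control library, with 129 at 12 h and 1.39 at 24 h, and cyp2k18 had 3748 against 14.9 FPKM. The gene of the glucuronosyltransferase ugt2a4 had 257 against 2.18 FPKM, ptgr1.2 253 against 0.713 FPKM, cyp3c3 137 against 1.01 FPKM and rnasel2 561 against 5.37 FPKM. The microRNA entries in this ranking had at most 7 reads, and no fold is given for them. Drug metabolism genes had a median of 2.61 (2.26 to 2.95), with 94 of 112 members at least 2-fold higher and 3 lower, and bile acid genes 2.18 (0.99 to 2.85), with 18 of 26 higher. The median was 1.73 for cholesterol synthesis (23 of 32 higher), 1.73 for glutathione and antioxidant genes (30 of 50), 1.63 for fatty acid oxidation (31 of 47), 1.55 for lipogenesis (-0.67 to 2.27, 18 of 29 higher and 7 lower), 0.94 for gluconeogenesis and glycogen (-0.25 to 1.48, 14 of 28 higher and 4 lower) and 0.79 for aryl hydrocarbon receptor targets (-0.23 to 2.06, 4 of 9 higher, with cyp1a at 105 against 37.7 FPKM). Ribosomal protein genes stood 1.27 higher (67 of 84 members). Beside these, the hepatocyte list stood 1.91 higher (1.75 to 2.35), with 65 of 75 members higher, the intestine list 2.79 higher and the exocrine pancreas list 1.26 higher.

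Cell cycle genes had a median of -4.79 (-5.34 to -3.95) at 48 h, with 37 of 41 members lower and 0 higher, and ovary markers -6.89 (-7.35 to -5.53), with all 27 lower. Macrophage (1.85), lymphocyte (1.48), neutrophil (1.46), biliary and progenitor (1.17), endothelial (0.98) and stellate and fibroblast markers (0.41) were above 0, as were interferon-stimulated (1.4), acute phase (1.12), immediate early (1.16), metal response (0.72), hypoxia (0.42), prostanoid (0.29), circadian clock (0.26), glycolysis (0.09) and autophagy genes (0.08). Of these, the intervals of the stellate and fibroblast, metal response, hypoxia, prostanoid, circadian clock, glycolysis and autophagy lists reached below 0. As at 12 h, the medians of immune and inflammation lists cannot tell an immune response from a different tissue content of the libraries. Median-ratio scaling gave 0.74 for stellate and fibroblast, 0.71 for hypoxia, 0.60 for prostanoid, 0.58 for circadian clock, 0.39 for glycolysis and 0.34 for autophagy genes. Erythrocyte markers had -0.04, a sign that changed with the scaling, proteasome genes -0.52 and testis markers -0.44 (-1.93 to 0.11), the last pair being -0.17 and -0.26 with median-ratio scaling. In all, 3964 entries were at least 2-fold higher and 5905 lower, and the median entry stood at -0.25, against -0.02 and -0.19 with median-ratio and trimmed-mean scaling.

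**Figure D2:**
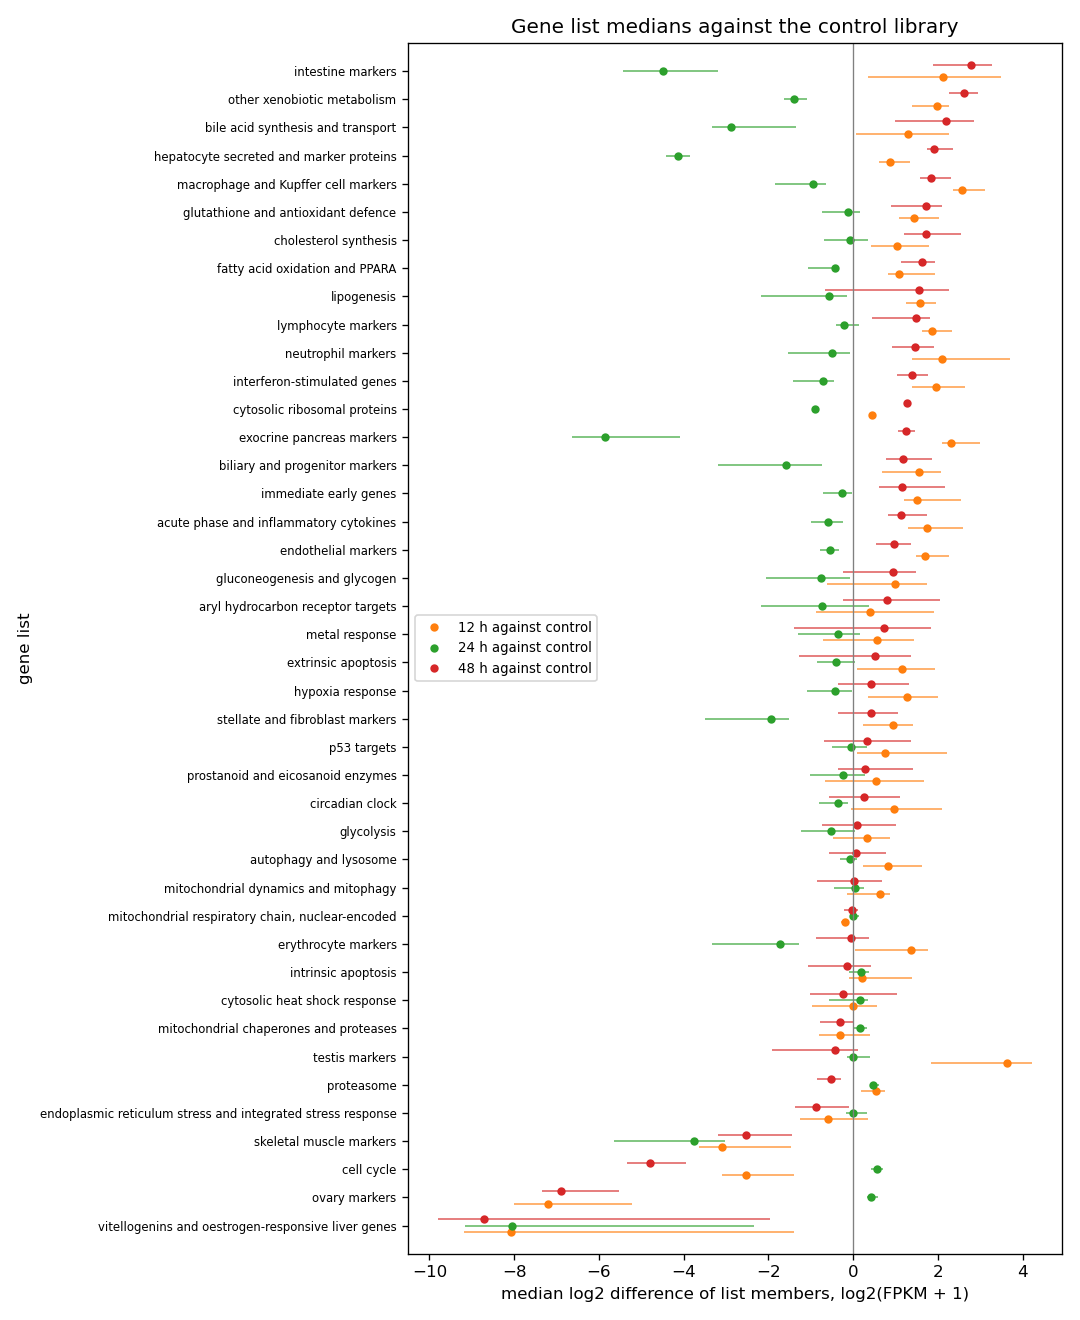
Median log2 difference from the control library, on the log2(FPKM + 1) scale of the horizontal axis, for each gene list on the vertical axis at 12, 24 and 48 h; points are medians over the members of a list and lines their 95% order-statistic intervals, which cover members and not replicates. The hepatocyte, intestine and exocrine pancreas lists lie above 0 at 12 and 48 h and below 0 at 24 h, and vitellogenins lie below 0 at all 3 times.

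Genes of the mitochondrial pathway of cell death went both ways against the control library. Their median was lower at 48 h than at 12 h, by an amount that depended on the scaling. From 12 to 48 h 17 of 31 members of the intrinsic apoptosis list were at least 2-fold lower and 0 higher as deposited. Of all 17500 entries, 26.1% were lower and 5.01% higher from 12 to 48 h. The list had a median of -1.10 (-1.63 to -0.34) at percentile 0 of random lists, and of -0.32 and -0.39 with median-ratio and trimmed-mean scaling. Against the control library the intrinsic apoptosis list had medians of 0.22 (-0.09 to 1.38), 0.19 (-0.09 to 0.38) and -0.15 (-1.06 to 0.43) at 12, 24 and 48 h, at percentiles 76.1, 72.0 and 77.0 of random lists of matched level, and the signs at 12 and 48 h changed with the scaling, the value at 24 h being 0.38 with median-ratio scaling. At 12 h 11 of its 31 members were at least 2-fold higher and 6 lower. The higher ones included the pro-apoptotic genes bada (43.8 against 0.531 FPKM in the control library), bbc3 (26.4 against 0.562), bik (85.6 against 3.71) and baxa (67.5 against 15.0) and the executioner caspase gene casp3b (49.0 against 0.977). At 24 h bbc3 stood at 0.223 and casp3b at 0.462 FPKM, and at 48 h at 9.56 and 14.5 FPKM. The lower ones at 12 h also included pro-apoptotic genes, pmaip1 (307 against 1238 FPKM) and bokb (2.56 against 60.8), beside birc5a (16.8 against 60.7). Hepatocyte, intestine and macrophage markers were also higher at 12 and 48 h than in the control library and lower at 24 h, but from 12 to 48 h the hepatocyte list stood at 1.12 and the intestine list at 0.62, against -4.25 for testis markers and -0.79 for macrophage markers. In that comparison the intestine list had 1.41 and 1.34 and macrophage markers -0.023 and -0.12 with median-ratio and trimmed-mean scaling. The ovary markers were lower at 12 and 48 h, as pmaip1, bokb and birc5a were. Extrinsic apoptosis genes had medians of 1.16 (0.09 to 1.93), -0.40 (-0.86 to 0.05) and 0.52 (-1.27 to 1.37), with 9 of 17 members higher at 12 h, fas among them at 30.5 against 1.75 FPKM. The value at 12 h was 0.74 and 0.59 with median-ratio and trimmed-mean scaling, and that at 48 h 0.87 with median-ratio scaling. Targets of p53 had 0.76 (0.09 to 2.23), -0.04 (-0.49 to 0.33) and 0.33 (-0.69 to 1.37), the value at 24 h changing sign with the scaling. That at 12 h was 0.34 and 0.18 with median-ratio and trimmed-mean scaling, and that at 48 h 0.68 with the former. As deposited, the extrinsic list lay at percentiles 94.9, 3.71 and 94.4 of random lists at 12, 24 and 48 h. The p53 list lay at 97.7, 15.6 and 95.4, of which only the value at 12 h was outside the central 95%. The cell cycle inhibitor gene cdkn1a stood at 2.14, 59.0, 2.95 and 7.04 FPKM in the 4 libraries.

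Nuclear genes of the respiratory chain had medians of -0.20 (-0.28 to -0.09), 0.00 (-0.04 to 0.13) and -0.03 (-0.22 to 0.12) at 12, 24 and 48 h, the last of which changed sign with the scaling. The value at 12 h was -0.63 with median-ratio and -0.79 with trimmed-mean scaling, and those at 24 and 48 h were 0.19 and 0.33 with median-ratio scaling. Of its 94 members, 8 were at least 2-fold higher and 9 lower at 12 h, 2 and 8 at 24 h, and 10 and 4 at 48 h. The cytochrome oxidase subunit gene cox6a2 had 151, 377, 0.745 and 389.5 FPKM in the control, 12 h, 24 h and 48 h libraries. It was higher at 12 and 48 h and lower at 24 h, as the hepatocyte list was. Mitochondrial chaperones and proteases had medians of -0.32, 0.15 and -0.32, the last changing sign with the scaling and the value at 12 h being -0.74 and -0.89 under these scalings and that at 24 h 0.34 with the former, with hspd1 at 128, 32.2, 156 and 49.0 FPKM. Mitochondrial dynamics and mitophagy genes had 0.63, 0.04 and 0.02, the value at 12 h being 0.22 and 0.07 under them and those at 24 and 48 h 0.23 and 0.35 with the former. As deposited, all of these lay within the central 95% of random lists. Genes of endoplasmic reticulum stress had medians of -0.59, -0.00 and -0.87, the value at 24 h changing sign with the scaling, with 19 of 46 members lower at 12 h and 20 at 48 h. The value at 12 h was -1.01 and -1.16 under these scalings, and that at 48 h -0.52 with the former. The chaperone gene hspa5 had 737, 288, 984 and 287 FPKM, while the stress factor gene ddit3 had 5.24, 52.5, 0.504 and 40.6 FPKM. The cytosolic heat shock list had 0.00, 0.16 and -0.23, with signs at 12 and 48 h that changed with the scaling and 0.35 at 24 h with median-ratio scaling. At 12 h the ribosomal (0.45), proteasome (0.54), metal response (0.57), glycolysis (0.32) and aryl hydrocarbon receptor (0.41) lists were above 0 as deposited and below 0 with trimmed-mean scaling, and prostanoid enzymes had 0.55, against 0.22 and 0.11 with median-ratio and trimmed-mean scaling. The intervals of the metal response, glycolysis, aryl hydrocarbon receptor and prostanoid lists reached below 0, and that of the endoplasmic reticulum list reached above 0.

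At all 3 times 42 entries were at least 2-fold higher than in the control library and 175 lower. Independent lists of these sizes would share 46.2 and 217 entries. Unchanged libraries simulated against the same control, with the spread of the 3 treated libraries, gave 1814 and 1909, values raised by the differences between the treated libraries themselves. Leaving out the 24 h library gave 3181 higher and 3817 lower, and leaving out the 48 h library 120 and 276. Differences at 12 and 48 h correlated across genes (r = 0.836, covariance 3.08). Those at 24 h ran against both (r = -0.254, covariance -0.584 with 12 h and r = -0.392, covariance -0.878 with 48 h). The simulations gave covariances of 2.47 to 2.48 for every pair. These too are raised by the differences between the treated libraries, so they do not measure the part of the shared control. The genes higher at all times were led by cyp2p10 (0.696, 14.1, 23.1 and 10.2 FPKM in the control, 12 h, 24 h and 48 h libraries), the bnip family member bnip4 (0.789, 9.04, 14.7 and 12.4 FPKM) and cyp3c2 (0.0656, 8.10, 3.25 and 10.4 FPKM), beside mir126a, which rested on 4 reads or fewer. The lysosomal nuclease gene dnase2 (0.784, 8.94, 9.39 and 5.33 FPKM) and the microsomal glutathione transferase gene mgst2 (15.6, 49.7, 49.4 and 47.6 FPKM, read ratio intervals of 2.78 to 3.83, 2.98 to 4.03 and 2.99 to 4.11) followed, with ms4a17a.9, mgrn1a, guca1ab.2 and cenpv. The lowest at all times were the 7 vitellogenin genes and the muscle parvalbumin genes pvalb1, pvalb2 and pvalb3. The vitellogenin and oestrogen list had medians of -8.08, -8.05 and -8.70, with 11, 11 and 10 of 12 members lower, and skeletal muscle markers had -3.08, -3.76 and -2.52.

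Between exposure times, 24 h stood apart from both others. Against 12 h, 4848 entries were at least 2-fold higher at 24 h and 6966 lower, a share of 41.0% higher that was 53.6% and 54.3% with median-ratio and trimmed-mean scaling. The median entry stood at -0.33, -0.28 and -0.49 from 12 to 24 h, 24 to 48 h and 12 to 48 h, and at 0.22, -0.20 and 0.14 with median-ratio scaling. Against 24 h, 5257 were higher at 48 h and 6628 lower. The lists moved accordingly, with the hepatocyte list at -5.20 from 12 to 24 h and 6.23 from 24 to 48 h, and ovary markers at 7.77 and -7.45. From 12 to 48 h 877 entries were higher and 4566 lower, a share of 16.1% higher that was 57.6% with median-ratio and 53.6% with trimmed-mean scaling, so that the excess of lower entries turned with the scaling. In that comparison the hepatocyte list stood at 1.12 (0.73 to 1.45), cholesterol synthesis at 1.09 (-0.07 to 1.58), the proteasome at -1.11 (-1.25 to -0.99), cell cycle genes at -2.34 and testis markers at -4.25. With median-ratio and trimmed-mean scaling the hepatocyte list stood at 1.91 and 1.84, cholesterol synthesis at 1.86 and 1.79, the proteasome at -0.34 and -0.41, cell cycle genes at -1.74 and -1.77 and testis markers at -3.87 and -3.84.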

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

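The mixture test below was chosen before its result was seen, and the other tests were chosen afterwards, on the same data.

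Medians of 7 lists lay at least 1 above 0 at some exposure time and at least 1 below 0 at another. With 1 library per time these differences were not tested. The hepatocyte list had 0.87, -4.13 and 1.91 at 12, 24 and 48 h. The exocrine pancreas list had 2.31, -5.85 and 1.26, and the intestine list 2.12, -4.50 and 2.79. Drug metabolism genes had 1.99, -1.40 and 2.61, and bile acid genes 1.29, -2.89 and 2.18. Biliary and progenitor markers had 1.55, -1.58 and 1.17, and erythrocyte markers 1.36, -1.73 and -0.041.

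Ovary and cell cycle genes stood high in the control and 24 h libraries, and liver, pancreas and intestine genes low at 24 h. A loss limited to hepatocyte transcripts is argued against by the exocrine pancreas list, at -5.85 at 24 h. A candidate explanation is a different tissue content of the libraries. A mixture of 0.746 times the 24 h library and 0.258 times the 48 h library was weighted on the ovary and hepatocyte lists alone. It predicted the control levels of 16085 entries outside all lists with r = 0.951 across genes, against 0.890 for the 24 h library alone. Within 2-fold lay 92.3% of entries, against 82.8%. The mixture cannot supply the vitellogenin and muscle RNA of the control library, which these entries leave out. The vitellogenin list stood at -8.05 and -8.70 at 24 and 48 h against control, and skeletal muscle markers at -3.76 and -2.52. The mixture cannot tell a different tissue content from changed expression within the tissue. Adding a library that holds the transcripts missing at 24 h would improve the prediction in either case. Whether a different tissue content would come from dissection, the fish chosen, a wrong label or exchanged sample, or the drug also stays open, since each time has 1 library.

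Vitellogenin genes stood high in the control library alone. Less liver RNA at 12 and 48 h is argued against by the hepatocyte list, at 0.87 and 1.91 there (at 12 h 0.44, interval 0.18 to 0.91, with median-ratio and 0.28, interval 0.033 to 0.76, with trimmed-mean scaling), and by fabp10a at 90.3% and 77.2% of its control level, where the 7 vitellogenins kept a median of 0.0940% and 0.0566%. At 24 h fabp10a kept 0.245% and the vitellogenins 0.126%, while the hepatocyte list stood at -4.13, so a lack of liver RNA cannot be told apart from a loss of vitellogenin RNA. Fish of different sex or reproductive state may also account for the pattern: testis markers stood 3.62 higher at 12 h and ovary markers were low at 12 and 48 h, but the sex of the fish is not in the labels, the 48 h library had neither marker set high, and the 24 h library held ovary markers at 0.42 with little liver RNA. This and an effect of the drug on vitellogenin RNA cannot be told apart with 1 library per group.

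Drug metabolism and glutathione genes stood high at 12 and 48 h and not at 24 h. More liver and intestine RNA in those libraries is a candidate explanation. Neither list median exceeded the higher of the hepatocyte and intestine medians (2.12 at 12 h and 2.79 at 48 h). Drug metabolism genes came near these values, at 1.99 and 2.61, and their intervals reached above them. The log2(FPKM + 1) scale understates changes of low genes, and many drug metabolism genes were low in the control library. The comparison therefore cannot decide for them. Relative to the hepatocyte list, drug metabolism genes lay 1.12 (0.52 to 1.38) and 0.70 (0.35 to 1.04) higher at 12 and 48 h, and glutathione genes at 0.57 (0.21 to 1.15), 4.0 (3.40 to 4.29) and -0.18 (-1.01 to 0.20) at 12, 24 and 48 h. These intervals take the hepatocyte median as fixed. Its own interval at 48 h, 1.75 to 2.35, overlaps the 2.26 to 2.95 of drug metabolism genes. At 12 h its 0.61 to 1.34 overlaps the 1.08 to 2.02 of glutathione genes. At 24 h the scale relative to the hepatocyte list decides nothing for drug metabolism genes, since 86 of 112 were too low in the control library to reach the -4.13 of the hepatocyte list even at 0 FPKM, against 15 of 50 glutathione genes. Nor does it for glutathione genes, whose list itself stood at -0.13 at 24 h, with 1 of 50 members higher. Their 4.0 reflects the -4.13 of the hepatocyte list. Induction by the drug stays open: both intervals at 12 h and that of drug metabolism genes at 48 h lie above 0. The glutathione interval at 48 h, however, reaches both sides of 0, and no library has the same tissue content without the drug.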

How the results depend on the processing

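The settings that leave out a library, keep only entries under 1 FPKM at 24 h or take list medians relative to the hepatocyte list were chosen after the data were seen, and the others before. No paired analysis was possible because each group has 1 library. The 14 counts stayed within 1.5 times without a filter and with library-scaled counts, and all 168 list medians without a filter stayed within the interval of the main value. Beyond that interval lay 65 with median-ratio scaling, 50 with trimmed-mean scaling, 28 with a pseudocount of 0.1 and 32 with 5, and no median of at least 1 in size changed sign in these. Of the named genes, 48 differences moved by more than their counting interval with a pseudocount of 0.1, and 48 did not. The numbers that moved and did not were 67 and 29 with a pseudocount of 5 and 27 and 69 with library-scaled counts. They were 17 and 79 with median-ratio and 15 and 81 with trimmed-mean scaling. None of at least 1 in size changed sign. With 1 library per group no setting tests a difference, and the depth limits values near 3 reads, or 0.102 to 0.176 FPKM for a gene of 1 kb. Where no cause is named, the cause was not tested.

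Counts at all 3 times were 42 higher and 175 lower. Calls at 2 or more times gave 3271 and 4001, which by construction admits more entries. Without the 24 h library they were 3181 and 3817, and without the 48 h library 120 and 276. Median-ratio scaling gave 1060 higher at 24 h, and 2622 higher and 1927 lower from 12 to 48 h, where trimmed-mean scaling gave 2320 and 2009. A pseudocount of 0.1 gave 938 higher and 4402 lower at 24 h and 139 higher at all 3 times. A pseudocount of 5, which by construction shrinks low entries, gave 3532 higher at 12 h, 253 higher and 1256 lower at 24 h, 2315 higher at 48 h, 4518 lower from 12 to 24 h, 3220 higher from 24 to 48 h, 561 higher and 1962 lower from 12 to 48 h, and 6 and 105 at all 3 times. A mean of at least 10 FPKM, with fewer entries, gave 2014 higher at 12 h, 246 and 1493 at 24 h, 1943 and 3573 at 48 h, 2451 lower from 12 to 24 h, 2241 and 3992 from 24 to 48 h, 553 and 1624 from 12 to 48 h, and 19 and 61 at all 3 times. Named symbols alone gave 370 higher at 24 h. Entries under 1 FPKM at 24 h, used only for comparisons without that library, gave 3457 and 187 at 12 h, 2440 and 173 at 48 h, and 459 and 1518 from 12 to 48 h. This selection largely fixes the counts at 12 and 48 h too, since an entry kept despite a low 24 h value is high in another library and the control levels follow those at 24 h (r = 0.870), so they say nothing about stability.

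List medians changed sign relative to the hepatocyte list, which by construction subtracts that list's own difference. At 48 h this gave -0.18 for glutathione, -0.28 for fatty acid oxidation, -0.35 for lipogenesis, -0.18 for cholesterol synthesis, -0.78 for acute phase, -0.51 for interferon-stimulated, -0.63 for ribosomal and -0.75 for immediate early genes. Markers at 48 h had -0.059 for macrophages, -0.45 for neutrophils, -0.43 for lymphocytes, -0.74 for biliary cells and -0.65 for the exocrine pancreas. At 24 h, where 86 of 112 drug metabolism genes and part of the other lists were too low in the control library to fall as far as the hepatocyte list, it gave 2.73 for drug metabolism, 1.24 for bile acids, 2.40 for erythrocytes, 2.55 for biliary cells, 2.19 for fibroblasts and 0.37 for skeletal muscle. Cholesterol synthesis from 12 to 48 h had -0.025 on this scale and -0.10 among entries under 1 FPKM at 24 h.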

Other observations

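The most abundant genes differed between the libraries as the marker lists did. In the control library they were the vitellogenins vtg1, vtg5, vtg2 and vtg7 with egg coat genes and translation factors, and at 24 h they were led by egg coat genes, zp3 first, at 5729 FPKM. At 12 h they included the pancreatic enzyme genes cela1.6, amy2a (5196 FPKM), prss1 and prss59.1 (9582 FPKM), and at 48 h the apolipoprotein genes apoa1b, apoa1a, apobb.1, apoc1 and apoea (8114 FPKM). The 10 most abundant genes took 6.95%, 8.04%, 5.04% and 11.7% of the scaled counts in the control, 12 h, 24 h and 48 h libraries. Metallothionein mt2 had 4991, 620, 4996 and 828 FPKM, high in the libraries with high ovary markers.

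Several genes were high at 12 h alone, as the testis list was (median 21.2 FPKM at 12 h and at most 0.542 in the other libraries). The neutrophil gene mpx was among them, and so was lect2.3, a leukocyte chemotaxin gene, with 326 FPKM at 12 h and at most 0.258 FPKM in the other libraries, while the neutrophil list as a whole stood higher at both 12 and 48 h. The clock gene nr1d4a had 0.482, 42.2, 0.0190 and 0.189 FPKM. Time of day at sampling is not in the labels used here. For this gene and the circadian clock list it cannot be told apart from exposure time. The heart muscle genes myl7 and cmlc1, among the highest at 48 h against 12 h, had 3979 and 1984 reads in the control library, 4 and 0 at 12 h, 2 and 1 at 24 h and 4390 and 2285 at 48 h. The microRNA entries among the named genes reached up to 528 FPKM, as dre-mir-184-2 did at 48 h, on 7 reads, because the entries are short.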
